A study of Mus musculus with 12 samples.

How the data were processed

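RNA was measured by mRNA sequencing in 12 libraries of hair follicle stem cells that had been sorted from mouse back skin. The labels place the libraries in 7 groups, of which 5 hold 2 libraries and 2 hold 1 library. Libraries were made with the TruSeq mRNA kit from Trizol-extracted RNA, per the labels' protocols. The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the mouse build mm9, without versions. How each tool was set is not given in the sources used here.

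The 3 deposited tables each hold 23735 gene models. One table compares the 2 anagen groups, one compares wild-type and conditional knockout cells of the second telogen, and a joint table holds 21 pairwise comparisons of all 7 groups. Expression is given as FPKM by the authors, with 1 pooled value per group and gene, so no value per library could be used. The log2 fold change per gene is the authors' own ratio of both FPKM values, per the file headers. The test statistic of each comparison is a score deposited by the authors, signed like the fold. The deposited p-value has a smallest value of 5e-05, and the deposited q-value equals a Benjamini-Hochberg adjustment over the tested genes to within 5.17e-07 in the anagen table and 5.25e-07 in the telogen table. In the joint table the q-value was adjusted by the authors over all comparisons together. A call there can therefore rest on a larger p than a call in a 2-group table. Tables were scaled separately: joint FPKM values differed from those of the anagen table by -0.08 on the log2 scale and from those of the telogen table by 0.06 in both groups. Levels from different tables are therefore not compared. No table gives counts or depths, so sequencing depth is unknown and no counting interval is given.

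The authors' test was taken as the main test, as chosen before the data were examined, and a gene was called at a deposited q below 0.05. The words rose, fell, higher and lower are used for called genes, or for the values of an unreplicated pair. Anagen knockout and heterozygous cells, and second telogen conditional knockout and wild-type cells, were compared within their own tables. Comparisons across those tables, and with the inducible knockout in second telogen, used the joint table. The authors' p-values rest on 2 libraries per group, and which sources of error their test models is not given in the sources used here. The standard error (SE) of a log2 fold was computed as the log2 fold divided by the deposited statistic. Across genes, the deposited p and a normal p from the statistic had Spearman correlations of 0.975 (anagen table) and 0.967 (telogen table). A rank correlation does not show that both p-values have the same size, so the SE and tests built on it are approximate. In 101 and 77 genes of those tables the deposited p was counted as not following the statistic. There the normal p was below 0.05 and the deposited p was not. Other mismatches between both p-values were not counted.

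The difference between the anagen and telogen knockout effects was tested per gene as a z value of the difference of both log2 folds, two-sided, with Benjamini-Hochberg adjustment at 0.05. Genes whose deposited p did not follow the statistic were left out of it, a choice made after the data were seen, and the count with those genes kept is given in the closing part. Overlaps of calls were tested with a one-sided Fisher exact test across genes, which are not independent replicates. For both telogen comparisons against wild type, which share control libraries, unchanged groups were simulated in 100 draws with a correlation of 0.5 between their z values.

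Gene lists for 25 pathways and cell types, holding 480 genes, were fixed before the data were examined. A further 2 lists, for antigen presentation and for glycolysis and hypoxia, were chosen after the data were seen. A list is described by its called members, by the members called with the authors' p adjusted over the list alone, and by the median of log2((FPKM + 1) ratio). With a pseudocount of 1, this ratio understates changes of genes at low FPKM. Each median was ranked among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description. A symbol on more than 1 row, which held for 160 symbols, was represented by its row with the highest mean FPKM. Genes with near-identical copies, such as the class I antigen presentation genes and the hair keratins, may share reads, and their values are uncertain to that extent.

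Genes were named by a rule fixed before the data were examined. For the anagen and telogen 2-group comparisons the rule took Foxc1, 8 further genes regardless of their values, the 8 highest and 8 lowest log2 folds among called genes with at least 1 FPKM in both groups, and up to 4 members per list by lowest p. For the joint comparisons it took Foxc1, the 5 highest and 5 lowest, and up to 2 members per list. Up to 10 genes called the same way in both 2-group tables, ranked by the smaller of their log2 folds, were also allowed. The deposited p and q values of the pair of single libraries, which have no replicates, were not used. For that pair the rule took Foxc1 and the 5 highest and 5 lowest among genes with at least 5 FPKM in either library. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here.

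The difference test was run on simulated data for 13033 genes, with 200 genes given a known difference. It recovered 3.0% of them at a log2 difference of 1, where 14.3% of calls were false, and 61.5% at a log2 difference of 2, where 3.15% were false. The 14.3% rests on few calls, as 6 changed genes were recovered there. The simulated noise was drawn with the same SE that the test uses, so it cannot show whether that SE is right. In simulated lists for the anagen comparison, 7.5% of random lists fell outside the 2.5 to 97.5 percentiles, and 100% of lists raised by 0.5 were found above them.

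Alternatives were a q threshold of 0.01, a filter at 1 FPKM, a minimum of 1.5-fold, the joint table, leaving out genes listed at 0, pseudocounts of 0.1 and 5, and centring on the median gene. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, with a fixed random seed. Start coordinates in the deposited tables count from 0, since 300 of 982 small RNA gene models then match RefSeq gene lengths, against 1 if they count from 1. Printed starts had 1 added. Krt15 was not tested by the authors in either 2-group table, where its status marks too much data, and Foxm1, Flg, Krt6a, Krt82, Krt85 and the hemoglobin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 were not found by symbol.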

Results

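The data describe hair follicle stem cells sorted from mouse back skin with and without the transcription factor Foxc1. Growth-phase (anagen) cells came from male mice at postnatal day 30 of a Black Swiss and C57BL/6 mix. Both anagen groups carried a tamoxifen-inducible Sox9CreER driver, and the 2 heterozygous libraries (Het) served as controls for the 2 inducible knockout libraries (iKO). The labels call the Het mice FOXC1-Sox9CreER-heterozygous, so their Foxc1 gene dose may differ from that of wild-type mice. Resting-phase (second telogen) cells came from Black Swiss mice, with a male at day 42 and a female at day 46 in both the wild-type group (WT) and the group with conditional knockout by K14Cre (cKO). A further 2 iKO libraries came from males of the mixed strain in second telogen at day 60. Shh-heterozygous females gave 1 library of first telogen at about day 23 and 1 library of an early anagen substage (anagen II) at about day 26. That genotype is from the cell type labels, while the titles of both libraries call them WT. Each FPKM value, fold and call below comes from the authors' deposited tables, as 1 pooled value per group, so no spread between libraries can be given for an FPKM value. Where the highest or lowest genes of a tested comparison are named, they are those among called genes with at least 1 FPKM in both groups.

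Foxc1, the targeted gene (XLOC_005118), lies on chromosome 13 from 31898515 to 31902504 in build mm9. In anagen its FPKM was 23.9 in Het and 1.40 in iKO cells, 17.0-fold lower, with a log2 fold of -4.09 (SE 0.30). In second telogen it was 26.5 in WT and 1.59 in cKO cells, 16.6-fold lower, with a log2 fold of -4.06 (SE 0.38). In the joint table, telogen iKO cells had 3.17 against 27.5 in WT cells, 8.66-fold lower. Foxc1 was called in all 3 comparisons. Among iKO cells it was 2.40-fold higher in telogen than in anagen, also a call. Among controls, Foxc1 was 22.5 in anagen Het and 27.5 in telogen WT cells and was not called, with q = 0.327 in the authors' deposited table. Control genotype differed with stage there. The Shh-heterozygous libraries had 42.6 in first telogen and 22.1 in anagen II.

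**Figure D1:**
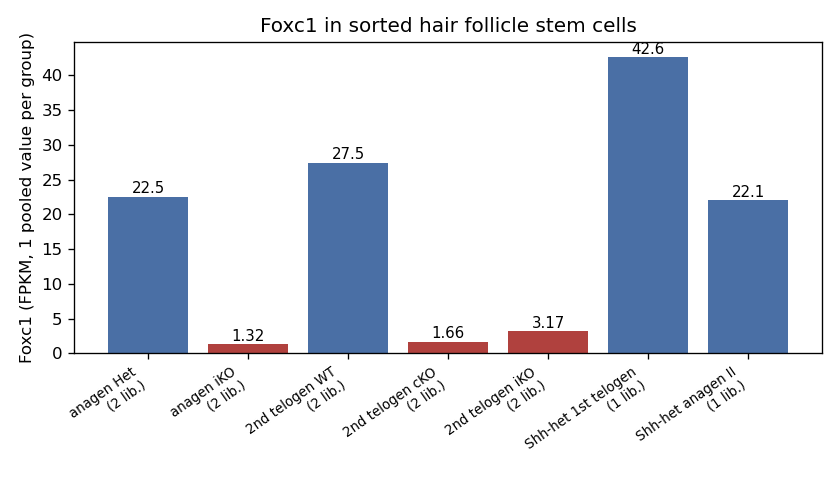
Foxc1 in FPKM (vertical axis) for each of the 7 groups of the joint table, with 1 pooled value per group as a bar, control groups in blue and knockout groups in red. The knockout groups had 1.32, 1.66 and 3.17 FPKM, against 22.1 or more in every control group.

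The anagen comparison asked which genes differ in growing-phase stem cells without Foxc1. Of 42 cell cycle genes 41 were higher in iKO cells. Lower were 8 of 20 quiescence-associated genes, 13 of 26 hair shaft and root sheath genes, 7 of 18 fibroblast genes and 7 of 25 BMP pathway genes. Of 13716 tested genes, 1408 were called, 711 higher and 697 lower in iKO cells. A change of at least 2-fold was found in 378 of the higher and 285 of the lower genes. With at least 1 FPKM in both groups, the 8 highest were Parp1, a DNA repair enzyme, at 8.05-fold, followed by BC100530, Cpa4, Mill1, Upk1b, the mitotic genes Depdc1a and Ndc80, and Pla2g7 at 4.59-fold. The level of Parp1, as of other genes with very large folds, has no value per library behind it, and a mapping difference between groups was not tested. Under the same minimum, the lowest after Foxc1 were the calcium pump gene Atp2a3 at 13.7-fold lower, Cadm3, Upk3bl, the secreted TGF-beta family member Gdf10, Nrep, Camk4, and the insulin-like growth factor binding protein Igfbp3 at 6.07-fold lower. Igfbp3 went from 269 to 44.3 FPKM (log2 fold -2.60, SE 0.24), and Nrep from 273 to 43.4 FPKM (log2 fold -2.65, SE 0.26).

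Of 42 measured cell cycle genes, 41 rose and none fell in anagen iKO cells, and 42 were called when adjusted over the list alone. Ndc80, a kinetochore component, rose 4.64-fold and Cdk1, the mitotic kinase, rose 4.25-fold from 6.90 to 29.4 FPKM (SE of log2 fold 0.26). The spindle checkpoint kinase Bub1 rose 3.85-fold and cyclin B1 (Ccnb1) rose 3.84-fold. The list median of 1.53 lay above all 10000 matched random lists.

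Among 20 quiescence-associated genes, 8 fell and none rose, with 10 called when adjusted over the list alone. Bmp6 fell 2.72-fold (SE of log2 fold 0.36), the growth factor Fgf18 2.14-fold (SE 0.34), Ctgf 1.86-fold and the transcription factor Foxp1 1.81-fold (SE 0.25). Among 24 bulge stem cell genes, which include Fgf18 and Foxp1, 6 fell and none rose, and 7 were called when adjusted over the list alone. Npnt fell 2.54-fold from 231 to 90.9 FPKM and Krt24 fell 1.66-fold. Nfatc1, a regulator of stem cell quiescence, fell 1.48-fold from 41.9 to 28.2 FPKM (SE of log2 fold 0.26), and the prolactin receptor Prlr fell 1.44-fold. Lgr5, with 59.2 in Het and 57.4 FPKM in iKO cells, and E-cadherin (Cdh1), with 141 and 131, were not called.

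In the BMP pathway list, 7 of 25 measured genes fell and 1 rose, with 9 called when adjusted over the list alone. The ligand Bmp2 fell 2.81-fold (SE of log2 fold 0.34), the secreted BMP antagonist Nog fell 3.01-fold and the BMP target Id2 fell 2.11-fold from 365 to 173 FPKM. The list median of -0.11 stood at the 3.34 percentile of random lists. In the WNT list 8 of 37 fell and none rose (9 adjusted over the list alone), among them Lgr6 at 2.47-fold, Wnt4 at 2.29-fold, Apcdd1 and Wnt7b. Of 12 Hedgehog genes, Cdon and Gli1 fell and none rose (3 adjusted over the list alone). In the FGF list 4 of 21 rose and 2 fell (6 adjusted over the list alone). Etv4, Dusp6 and Etv5, which FGF signalling through the ERK kinases induces, rose 3.53-, 2.98- and 2.17-fold, and the receptor Fgfr2 fell 2.31-fold. In the Notch list 3 of 17 rose, which were Lfng, Jag1 and Nrarp, and Hey1 fell (5 adjusted over the list alone). In the TGF-beta list 1 of 18 rose and 2 fell (4 adjusted over the list alone), with Ltbp1 2.01-fold lower.

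Of 19 activated keratinocyte genes, 6 rose and none fell, and 6 were called when adjusted over the list alone. Lcn2 rose 5.03-fold, keratin Krt16 3.75-fold and the EGF family ligand Hbegf 2.23-fold. Of 25 epidermal differentiation genes, 5 rose and 1 fell (7 adjusted over the list alone). Krtdap rose 2.57-fold and Krt1 1.57-fold, and Klf4 fell 1.48-fold. Of 29 cell-cell adhesion genes 3 rose and none fell (3 adjusted over the list alone), with Epcam at 2.29-fold. In the integrin and basement membrane list 1 of 23 rose, which was Thbs1, and 3 fell (4 adjusted over the list alone), with Npnt and Col7a1 among them. Gbp2 and Ifit2 rose among 17 interferon response genes (3 adjusted over the list alone).

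Genes listed as markers of other cells also differed between the anagen groups. Of 26 hair shaft and root sheath genes 13 fell and none rose (16 adjusted over the list alone), with Krt33b 10.9-fold, Krt81 8.40-fold and Krt33a 4.30-fold lower. Of 18 fibroblast genes 7 fell and 1 rose (10 adjusted over the list alone), with Col1a2 at 2.44-fold and Col6a1 at 2.21-fold. The hair shaft and fibroblast list medians were -0.55 and -0.45, below all 10000 random lists. Col6a1 had 137 FPKM in Het cells. Between controls, 10 fibroblast genes were higher in anagen Het than in telogen WT cells and 3 were lower, which were Col6a2, Mmp2 and Col6a1. Between controls the fibroblast list thus did not move as 1 set. In anagen iKO against Het cells 17 of 18 members had a smaller value, called or not, and 1 had a larger value. Whether the iKO sort held fewer fibroblasts was not tested and stays open. Of 21 immediate early and stress genes 3 rose and 5 fell (12 adjusted over the list alone), with Ier3 1.89-fold higher and Dusp1 1.76-fold lower. Vwf and Tek fell among 15 endothelial and pericyte genes (2 adjusted over the list alone), Mitf and Gpnmb among 12 melanocyte genes (3), and Ngfr among 8 Schwann and nerve genes (1). Of 18 immune genes, Cd74 rose 2.47-fold and no other was called, with 1 adjusted over the list alone. None of 19 junctional zone and sebaceous genes, 14 muscle and adipocyte genes, 5 sex-linked genes or 2 blood genes was called, also when adjusted over the list alone.

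The telogen comparison asked the same of resting cells from mice that lacked Foxc1 in K14Cre-expressing epithelium. Of 42 cell cycle genes 36 were higher in knockout cells. Lower were 9 of 20 quiescence-associated genes, 7 of 21 immediate early and stress genes and 6 of 25 BMP pathway genes. Of 13551 tested genes, 897 were called, 508 higher and 389 lower in cKO cells, and 410 and 262 of these changed at least 2-fold. In the joint table the same groups gave 885 higher and 792 lower genes. Among called genes with at least 1 FPKM in both groups, the highest was Wif1, a secreted WNT inhibitor, at 11.1-fold, from 14.7 to 163 FPKM (log2 fold 3.47, SE 0.33). Top2a, Cdk1, Birc5 and Ccnb2, all mitotic genes, rose 8.07- to 9.20-fold, and the small RNA genes Rpph1 and Rmrp and the class I-like gene Mill1 completed the 8. Under the same minimum the lowest was Pde4dip, 212-fold lower, from 1033 to 4.87 FPKM, followed by Ercc2 at 21.7-fold, Pcolce2 at 17.9-fold and Foxc1, without values per library to show whether 1 library set these levels. Igfbp5 fell 9.55-fold, Nrep 6.97-fold (SE of log2 fold 0.35), Gm12505 6.32-fold and Igfbp3 6.31-fold (SE 0.34).

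Of 42 cell cycle genes, 36 rose and none fell in telogen cKO cells, and 39 were called when adjusted over the list alone. Ndc80 rose 15.6-fold, Bub1 11.3-fold, the proliferation marker Mki67 10.2-fold from 0.983 to 9.99 FPKM, and Aurkb 9.66-fold. The list median was 1.65, above all 10000 random lists. It depended on the pseudocount, with 0.82 at a pseudocount of 5, where the anagen median was 1.09, so the order of both medians is not fixed. WT levels of these genes were low, since Ndc80 and Bub1 had 0.164 and 0.169 FPKM.

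Of 20 quiescence-associated genes, 9 fell and 1 rose, with 11 called when adjusted over the list alone. The cyclin-dependent kinase inhibitor Cdkn1c fell 4.53-fold, the WNT inhibitor Sfrp1 3.34-fold from 145 to 43.5 FPKM, Bmp6 3.09-fold (SE of log2 fold 0.48) and Fgf18 2.54-fold (SE 0.36). The riser was Wif1, which inhibits WNT signalling. Foxp1 fell 1.77-fold. Of 24 bulge genes 2 fell, which were Fgf18 and Foxp1, and Aspn rose 2.64-fold (3 adjusted over the list alone). Cd34 had 848 FPKM in WT and 385 in cKO cells and was not called. Of the other genes named in advance, Nfatc1 (72.7 in WT and 76.9 FPKM in cKO cells), Bmp2 (log2 fold -0.02), Cdh1 (132 and 162), Lgr5 (97.9 and 89.0) and Prlr (26.9 and 14.3) were not called.

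Of 25 BMP pathway genes 6 fell and none rose (7 adjusted over the list alone). Smad9 fell 2.34-fold and the BMP targets Id3 and Id2 fell 2.17- and 2.07-fold. In the WNT list 5 of 37 rose and 1 fell (7 adjusted over the list alone), with the transcription factor Lef1 4.03-fold higher, Porcn 1.92-fold higher and Sfrp1 lower. In the Hedgehog list 2 of 12 genes rose and 1 fell (4 adjusted over the list alone), with Gli1 1.62-fold higher and Hhip, which antagonises the pathway, 4.81-fold lower. In the FGF list 4 of 21 fell and 1 rose (6 adjusted over the list alone), with Dusp6 2.35-fold and Fgf1 2.28-fold lower and Fgfbp1 higher. In the Notch list Hes1 and Numb fell and Nrarp rose among 17 genes (3 adjusted over the list alone). Inhbb rose 1.99-fold and was the single call among 18 TGF-beta genes (1 adjusted over the list alone).

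Of 19 activated keratinocyte genes 4 rose and 1 fell (6 adjusted over the list alone), with the defensin Defb6 3.13-fold and Krt16 2.89-fold higher and Hbegf 2.20-fold lower. Sprr1b, Tgm3 and Casp14 rose among 25 epidermal differentiation genes (6 adjusted over the list alone), and Dsg1b and Cldn1 among 29 adhesion genes (2). The single call among 24 integrin and basement membrane genes was Itgb6, 2.35-fold lower (1 adjusted over the list alone). Krt79 rose 4.24-fold and Elovl3 2.98-fold, and Scd3 and Plet1 fell, among 19 junctional zone and sebaceous genes (5 adjusted over the list alone). Gbp2 rose and Usp18 fell among 17 interferon response genes (4 adjusted over the list alone).

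Of 21 immediate early and stress genes, 7 fell and none rose in cKO cells, with 13 called when adjusted over the list alone and a median of -1.09. Nr4a1 fell 3.87-fold, Ier2 2.87-fold from 562 to 195 FPKM, Egr3 2.64-fold and Ier3 2.15-fold. Krt32 and Krt73 rose and Dlx3 fell among 26 hair shaft and root sheath genes (4 adjusted over the list alone). Among 18 fibroblast genes Col1a1 rose 6.22-fold and Mmp2 fell 3.36-fold (3 adjusted over the list alone). Flt1 rose among 15 endothelial and pericyte genes (2 adjusted over the list alone), Cd68 fell among 18 immune genes (1) and Mitf fell among 12 melanocyte genes (2). None of the muscle and adipocyte, Schwann and nerve, sex-linked or blood genes was called, also when adjusted over the list alone.

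**Figure D2:**
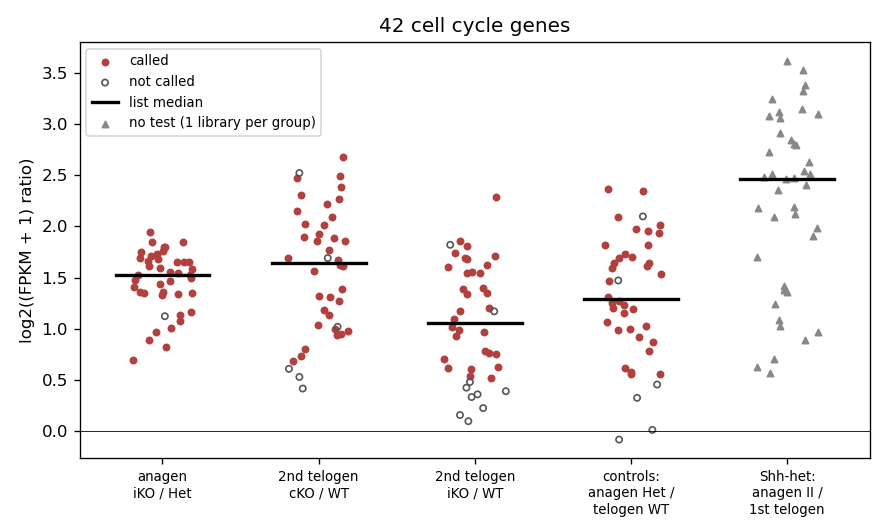
Log2((FPKM + 1) ratio) (vertical axis) of 42 cell cycle genes in 5 comparisons, with each gene as a point, filled where called, and a line at the list median; grey triangles are the pair of single libraries, for which no test was used. Medians were 1.53 and 1.65 in the anagen and telogen 2-group comparisons, 1.05 for telogen iKO over WT, 1.29 for anagen over telogen controls and 2.47 for the Shh-heterozygous pair, all with a pseudocount of 1.

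Calls in the anagen and telogen comparisons, which share no library, overlapped in both directions. Among 13085 genes tested in both, 290 were higher in both knockouts, where 25.9 would be shared by independent lists of 691 and 490 genes (one-sided Fisher exact p = 4.06e-261 across genes). Lower in both were 167 genes, against 18.1 from lists of 631 and 375 (one-sided Fisher exact p = 1.87e-123). The latter count was 275 in the joint table and 99 at q below 0.01 in both. Of the 290 genes, 36 belong to the cell cycle list. Ranked by the smaller change, the first 10 were Fzd9, a WNT receptor gene that fell 37.2-fold in anagen and 29.3-fold in telogen, Foxc1, Atp2a3, Serpina3b, Cadm3, Nell1, Sprr1b, BC100530, Gdf10 and Nrep. Sprr1b and BC100530 rose and the others fell. Nell1 was listed at 0 in telogen cKO cells. In opposite directions, without a test of these counts, 13 genes rose in anagen and fell in telogen (19.8 for independent lists), among them Dusp6, Hbegf, Egr2, Egr3 and Ier3. In the other direction were 17 genes (23.6 for independent lists), among them Col1a1, Krt73, Gli1 and Wnt7b. Across 13033 genes, which are not independent replicates, the log2 folds had a Spearman correlation of 0.43.

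**Figure D3:**
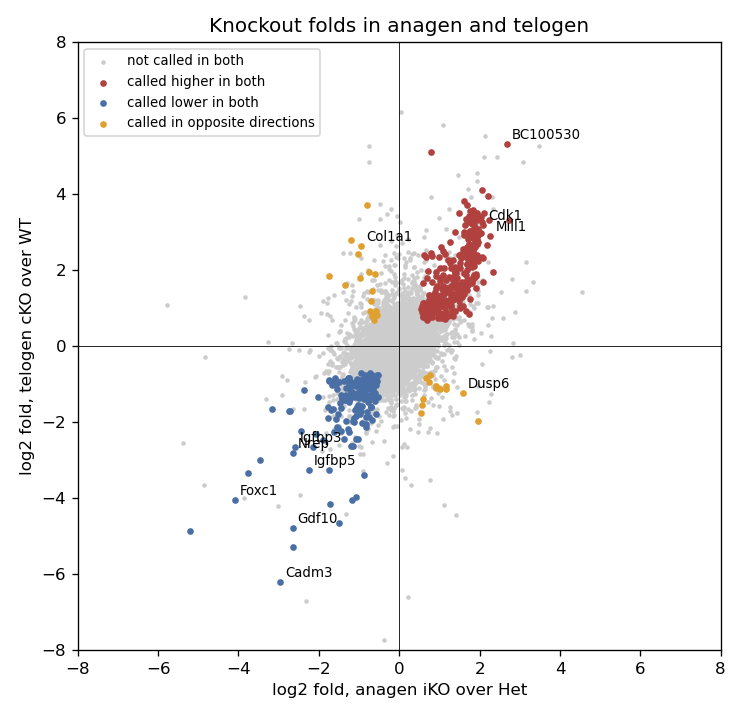
Log2 fold of iKO over Het in anagen (horizontal axis) against log2 fold of cKO over WT in second telogen (vertical axis), with each gene as a point. The 290 genes higher in both are red, the 167 lower in both are blue, genes called in opposite directions are orange, and Foxc1 lies at -4.09 and -4.06.

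The difference between both knockout effects was then tested itself, since a call in one table alone does not show a difference. Of 12939 genes, 85 differed, with 50 log2 folds higher and 35 lower in telogen than in anagen. The count depended on the form of the test: 45 genes with a more cautious SE, 133 in the joint table for this difference between anagen and telogen knockout effects, and 129 with genes kept whose deposited p does not follow the statistic. Cre driver, control genotype, strain, age and sex differed with stage between both tables, so a difference cannot be assigned to stage. Wif1 had a log2 fold of -0.30 in anagen and 3.47 in telogen, Lef1 of -0.77 and 2.01, and Col1a1 of -0.94 and 2.64. Dusp6 had 1.58 in anagen and -1.23 in telogen, and Hbegf had 1.16 and -1.13. Of 200 simulated genes with a log2 difference of 1 the test recovered 3.0%, so most differences of that size would be missed if the SE is right.

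Inducible knockout cells in second telogen have no control of their own stage, strain and driver, and were set against WT telogen cells in the joint table. Higher were 32 of 42 cell cycle genes, 9 of 19 activated keratinocyte genes and 10 of 19 junctional zone and sebaceous genes. Of 13714 tested genes 1769 were called, 962 higher and 807 lower. With the authors' p adjusted within this comparison alone, over genes with at least 1 FPKM in either group, 707 were higher and 559 lower. The highest were Ccnf at 19.8-fold, Fkbp5, Elovl3, the glycolysis regulator Pfkfb3 and Mcam. The lowest were Ddhd1 at 9.53-fold, Grik1, Foxc1, Krtap17-1 and Lce1m. Of 42 cell cycle genes 32 rose and none fell (35 adjusted over the list alone, median 1.05), with Ndc80 11.7-fold and Bub1 8.59-fold higher. Of 19 activated keratinocyte genes 9 rose and none fell (9 adjusted over the list alone), Defb6 by 2.72-fold. Of 19 junctional zone and sebaceous genes 10 rose and 1 fell (12 adjusted over the list alone), with Elovl3 at 8.74-fold and Krt79 at 4.05-fold.

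In the quiescence-associated list 4 of 20 rose and 2 fell in telogen iKO cells (6 adjusted over the list alone), with Fgf18 5.99-fold lower and Wif1 2.43-fold higher. Of 24 bulge genes 5 rose, Aspn by 2.35-fold, and 1 fell (6 adjusted over the list alone), although the list median was -0.24. Smad9 fell 1.67-fold and Bmp4 rose 2.51-fold among 25 BMP genes, of which 3 fell and 1 rose (3 adjusted over the list alone). Of 24 integrin and basement membrane genes 7 fell and 1 rose (11 adjusted over the list alone), with Col4a2 3.12-fold lower and Col4a1 also lower. Of 18 fibroblast genes 5 fell and none rose (7 adjusted over the list alone), among them Col1a1 at 2.27-fold, and of 21 immediate early genes 3 rose and 3 fell (7). Of 5 sex-linked genes 4 rose and 1 fell (5 adjusted over the list alone): Xist had 46.7 FPKM in WT and 0.0874 in iKO cells, since WT libraries came from a male and a female and iKO libraries from males. Strain, age, driver and sex differed together between these groups and cannot be separated from the loss of Foxc1.

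Of the 290 genes higher in both 2-group comparisons, 210 were also called higher in telogen iKO cells, and of the 167 lower genes 89 were also called lower. Within the joint table, telogen cKO and telogen iKO cells shared 414 higher genes, against 57.6 for independent lists, and 267 lower genes, against 47.2. In simulation, unchanged groups sharing the control gave 0 shared calls after adjustment, as unchanged genes are rarely called. At an unadjusted p below 0.05, 63.3 simulated genes were higher in both, against 8.36 for independent lists. Both comparisons used the same 2 WT libraries, which cannot be split, so part of the excess may come from the shared controls. Anagen and telogen iKO comparisons, which share no library, had 309 higher genes in common, against 49.5, and 215 lower genes, against 39.9.

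Stage was compared in iKO cells and in controls. In iKO cells 4572 of 13787 genes differed between telogen and anagen, 2433 higher and 2139 lower in telogen. Pde4dip, which was low in telogen cKO cells and so did not follow stage alone, was 121-fold higher in telogen. Pyy was 50.8-fold, Aspn 38.1-fold, and the immediate early genes Fosb and Atf3 28.2- and 27.0-fold higher in telogen. Gnmt was 163-fold, the connexin gene Gjb2 118-fold, Tagln 20.7-fold, Krt71 19.6-fold and Pla2g7 18.9-fold lower. Of 42 cell cycle genes 41 fell and none rose in telogen (41 adjusted over the list alone), Mcm5 by 5.85-fold. Of 20 quiescence-associated genes 14 rose and 2 fell (17 adjusted over the list alone), Ctgf by 18.5-fold. Of 26 hair shaft genes 16 fell and 1 rose (18 adjusted over the list alone), and Krt33b and Krt36 were listed at 0 in telogen. Of 21 immediate early genes 17 rose and 2 fell (20 adjusted over the list alone), and of 18 immune genes 11 rose and 1 fell (13). Other cell markers differed too. Of 15 endothelial and pericyte genes 8 fell and none rose (8 adjusted over the list alone), and of 18 fibroblast genes 7 fell and 4 rose (13), with Col3a1 42.8-fold and Dcn 38.6-fold lower. Of 25 epidermal differentiation genes 18 rose and 1 fell (20 adjusted over the list alone), Klf4 by 13.4-fold, and of 19 junctional zone and sebaceous genes 14 rose and 2 fell (16), Fa2h by 11.4-fold. Age, 60 against 30 days, differed with stage.

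In control cells 3539 of 13932 genes differed, 1655 higher and 1884 lower in anagen Het than in telogen WT cells. Gnmt was 41.9-fold, the matrix gene Bgn 31.6-fold, Mcam 14.8-fold, Mfap2 12.8-fold and Ucp2 11.5-fold higher in anagen. Pde4dip was 203-fold, Lce1m 26.6-fold, Wfdc3 20.1-fold and Ngef 19.8-fold lower. As Pde4dip was low in telogen cKO cells too, it did not follow stage alone. Of 42 cell cycle genes 36 rose and none fell in anagen (37 adjusted over the list alone), with Ndc80 and Bub1 both 10.5-fold higher. Of 20 quiescence-associated genes 14 fell and 2 rose (17 adjusted over the list alone), Ctgf by 17.3-fold. Of 26 hair shaft genes 15 rose and none fell (17 adjusted over the list alone), and Krt33b and Krt81 were listed at 0 in telogen. Of 18 fibroblast genes 10 rose and 3 fell (13 adjusted over the list alone), with Col3a1 at 0.382 FPKM in telogen and 28.7 in anagen. Of 15 endothelial and pericyte genes 9 rose and 1 fell (11 adjusted over the list alone), and of 12 melanocyte genes 6 rose and 1 fell (8). Of 18 immune genes 7 fell and none rose (8 adjusted over the list alone), Cd207 by 12.8-fold, and of 25 epidermal differentiation genes 15 fell and 2 rose (18), Lor by 16.5-fold. Of 21 immediate early genes 17 fell and 1 rose (20 adjusted over the list alone, median -2.29), Atf3 from 1816 to 129.7 FPKM and Zfp36 from 1469 to 123 FPKM. Xist had 0.0802 FPKM in anagen Het and 46.7 in telogen WT cells. Stage, strain, driver, control genotype (heterozygous against wild type), sex and age differed together.

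The Shh-heterozygous pair followed the step from first telogen to anagen II with 1 library on each side, so the values describe these libraries and have no replicate check. By the rule fixed in advance, the extremes were small RNA genes listed at 0 in one library: Snord99, Snord52, Snord65, Snord12 and Snord34 in first telogen, and Scarna2, Mir7041, Mir23a, Snord38a and Mir3087 in anagen II. Outside small RNAs, a choice made after the values were seen, Gjb2 was 104-fold, Slc7a8 64.4-fold, Fhod3 50.9-fold, Lrrc75b 47.1-fold and Gnmt 46.6-fold higher in anagen II. The 5 lowest by the same choice were 4930470H14Rik at 118-fold, Gm17644 at 106-fold, the shared gene model of Dancr and Snora26 at 73.5-fold, A630089N07Rik at 62.8-fold and Fosb at 45.2-fold lower. The cell cycle list had a median of 2.47 and the hair shaft list of 0.97, both above all 10000 random lists. Medians of the bulge, quiescence-associated, immediate early, immune and fibroblast lists were -1.11, -1.10, -2.28, -1.64 and -1.38, below all 10000. The first telogen library stood apart from the other groups, with 1849 genes listed at 0 against 5856 in the anagen II library, and 464468 FPKM in the single gene Mir6236.

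**Figure D4:**
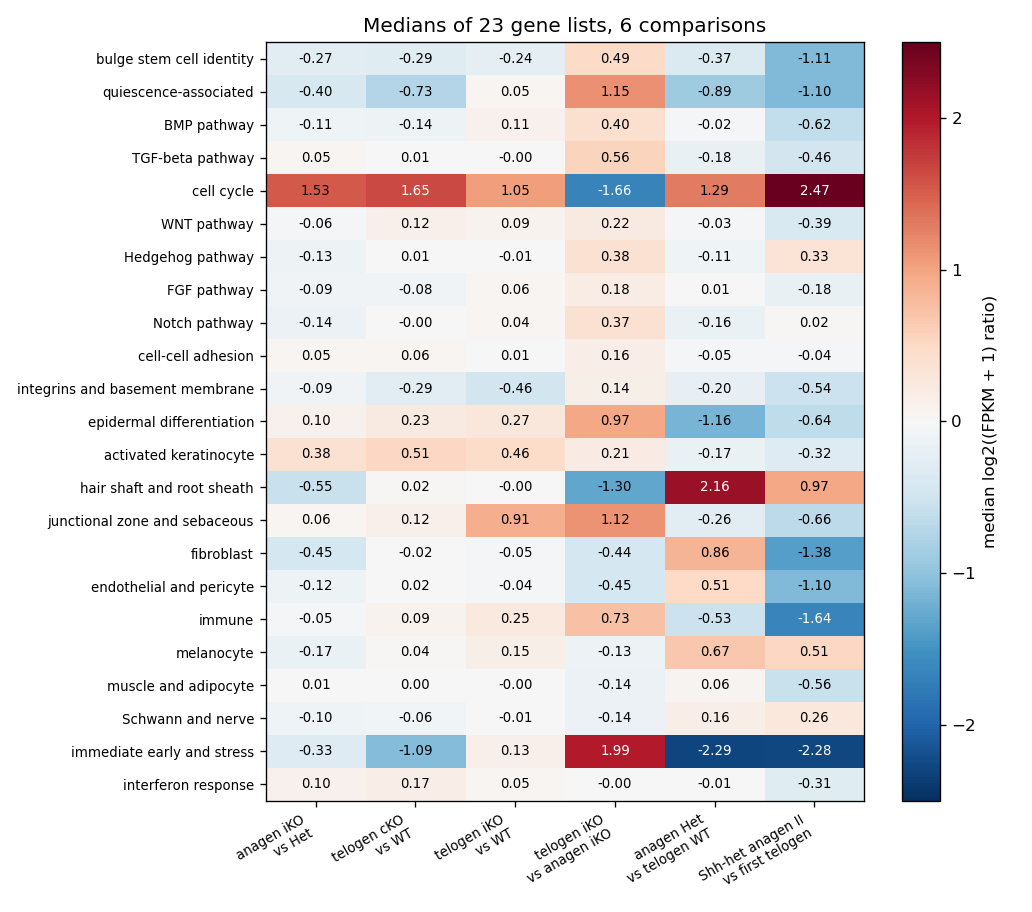
Median log2((FPKM + 1) ratio) of 23 gene lists (rows) in 6 comparisons (columns), with the first-named group over the second, red for higher and blue for lower. The cell cycle row is positive in every knockout over control column (1.53, 1.65 and 1.05), and the immediate early row is -0.33 and -1.09 in the 2-group comparisons and 0.13 for telogen iKO over WT.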

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

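The tests of scaling and of hair shaft and root sheath cells were chosen only after the results were seen. So were both tests on immediate early genes and the check of each difference with a more cautious SE. The test on stage genes was set before its result was seen, though the requirement that its median lie below 0 by more than the spread of random lists was applied after.

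A test of the difference between the log2 folds in anagen and telogen picked out 85 genes, and 22 of the genes named by rule are among them. Cre driver, control genotype, strain, age and sex differed with stage, so these differences cannot be assigned to stage. In 10 of the 22 genes the telogen fold lay above the anagen fold. The differences on the log2 scale were 4.52 for Krt73, 3.77 for Wif1, 3.57 for Col1a1, 2.98 for Rmrp, 2.78 for Lef1, 2.65 for BC100530, 2.40 for Rpph1, 1.72 for Krt79, 1.64 for Lgr6 and 1.49 for Wnt7b. In 12 the telogen fold lay below. The differences were -7.35 for Pde4dip, -5.84 for Ercc2, -3.24 for Cadm3, -2.81 for Dusp6, -2.66 for Camk4, -2.44 for Pcolce2, -2.29 for Mmp2, -2.29 for Hbegf, -2.02 for Ier3, -2.00 for Egr3, -1.53 for Egr2 and -1.46 for Ier2. With the SE taken from the deposited p wherever that was larger, 12 of the 22 still passed, which were Krt73, Wif1, Col1a1, Lef1, Pde4dip, Ercc2, Dusp6, Mmp2, Hbegf, Ier3, Egr3 and Egr2. The other 10 did not, BC100530, Cadm3 and Camk4 among them. Because the deposited p cannot go below 5e-05, this form inflates the SE of genes at that limit with very large folds. For such genes failing it does not by itself show weaker evidence. Rpph1 was not at that limit in telogen, where the authors' test gave p = 0.0004, so the limit does not account for every failure. The reason for failing was not separated for each of the 10 genes.

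Pde4dip had 1081 FPKM in telogen WT and 496 in telogen iKO cells of the joint table, against 5.07 in telogen cKO, 5.32 in anagen Het and 4.09 in anagen iKO cells. Ercc2 had 183 in telogen WT, 8.45 in telogen cKO and 193 in telogen iKO cells. Without values per library it cannot be seen whether 1 library set these levels.

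The rise of cell cycle genes in Foxc1 knockout cells, with 41 and 36 of 42 genes called, was weighed against 3 explanations. A general shift in scaling would move all genes. The median over genes with at least 1 FPKM was -0.0140 in anagen, where it was farthest from 0. The deposited values therefore hold no general shift as large as the rise. A difference in total RNA between groups cannot be judged, since scaling of the values can remove it. More hair shaft and root sheath cells in the anagen knockout sort would raise the genes listed for them. The median of that list was instead -0.55, below all random lists. Most of its members are keratins and it holds no separate set of hair matrix genes, so more matrix cells cannot be judged from it. Telogen knockout cells that had gone on to anagen could raise genes of anagen onset. This set held 137 genes at least 4-fold higher in the Shh-heterozygous anagen II library, outside the cell cycle list and not called in anagen. They were chosen against the first telogen library, which had 464468 FPKM in Mir6236 and 1849 genes listed at 0. The set may therefore partly reflect that library and not anagen onset. The median of the set was -0.0141, at the 37.1 percentile, within the spread of random lists. Of 115 tested members, 16 were called higher and 6 lower, and 29 were called when adjusted over the list alone. Over all genes, 508 of 13551 were called higher and 389 lower. The set thus held larger shares of both, mainly of higher calls, so its calls go partly with the explanation though its median does not. That explanation stays open, as does more division of cells without Foxc1, which was not tested separately, and it rests on 1 library per stage.

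Immediate early genes were lower in telogen cKO than WT cells, with 7 of 21 called and a median of -1.09. A fall with Foxc1 loss regardless of stage and driver would recur in telogen iKO cells, where the median was 0.13, at the 92.7 percentile, and in anagen iKO cells, where it was -0.33, below all random lists, with 5 genes called lower and 3 higher. Handling of the cells before lysis could also move these genes. Their median differed by -2.29 between anagen Het and telogen WT cells, so controls differed by more than knockout and control did. However, stage, strain, driver, control genotype, sex, age and preparation differ together there. Handling, a general effect of Foxc1 loss and one particular to the conditional knockout cannot be told apart, since no label records handling per library.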

How the results depend on the processing

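Alternatives chosen after the data were seen were leaving out small RNAs or the cell cycle list, the larger SE, and keeping genes whose deposited p does not follow the statistic. The filter at 1 FPKM, the 1.5-fold minimum and leaving out genes at 0 or small RNAs kept every count they were run on within 1.5 times. Log2 folds of named genes were recomputed only with a pseudocount of 1 and in the joint table, and none changed sign. That is no check of direction, since a pseudocount keeps the order of both groups and joint values were shifted alike in both. The sign changed in 14 of 570 alternative list medians, each of a list whose median lay inside the central range of random lists, with centring on the median gene, members of at least 1 FPKM or a pseudocount of 0.1. At q below 0.01, 424 genes were lower in anagen iKO and 232 in telogen cKO cells, 607 were higher and 408 lower in telogen iKO than WT cells, and 99 were lower in both 2-group comparisons, as a stricter threshold must give fewer. In the joint table, 885 genes were higher and 792 lower in telogen cKO cells. There 396 genes were higher and 275 lower in both knockouts. The test of the difference between anagen and telogen knockout effects called 133 genes there. A joint call can rest on a larger p. The authors' test of Usp18 in telogen iKO over WT cells gave p = 0.01115 with a joint q of 0.0455. In the telogen table the authors' test of Krtdap in cKO over WT cells gave p = 0.0044 with q = 0.0625. How much of the joint counts this accounts for was not tested, and the difference test does not use the deposited q. Within the 2-group comparisons, the 290 genes higher in both became 254 without the cell cycle list. The same difference test called 45 genes with the SE from the deposited p where larger, by construction a stricter form, and 129 with genes kept whose deposited p does not follow the statistic. Cell cycle medians were 1.09 with a pseudocount of 5 and 1.71 with 0.1 in anagen, and 0.82 and 2.27 in telogen, since these genes have low FPKM. Of the alternative list medians 184 moved by more than the spread of random lists, and of 471 alternative log2 folds of named genes 57 moved by more than 1 SE and 20 became calls in the joint table. No paired analysis was possible because each group has 1 pooled value, and leaving out a replicate and the replicate block were not run for the same reason. Depth is unknown and limits what can be said of genes near 0 FPKM.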

Other observations

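Both lists in this part, and all tests on them, were chosen after the data were seen, from genes that rose in the 2-group comparisons, so their counts are not independent evidence of a direction.

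Of 15 genes of antigen presentation on class I molecules, 10 rose in anagen iKO cells and 1 fell, with 12 called when adjusted over the list alone and a median of 0.70. The immunoproteasome genes Psmb8 and Psmb9 rose 3.63- and 2.64-fold, the class I light chain B2m rose 2.27-fold from 263 to 596 FPKM, and Nlrc5, a regulator of class I genes, rose 2.25-fold. In telogen cKO cells 10 of 15 rose and none fell (11 adjusted over the list alone, median 1.11), with Psmb8 3.66-fold, Psmb9 3.09-fold and H2-K1 2.62-fold higher. H2-T23 went opposite ways, with a log2 fold of -0.68 in anagen iKO and 1.44 in telogen cKO cells. Among controls, 11 of these genes were lower and 1 higher in anagen Het than in telogen WT cells.

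Of 35 genes of glycolysis and the hypoxia response, 11 rose and none fell in anagen iKO cells (14 adjusted over the list alone), 17 rose and 1 fell in telogen cKO cells (23), and 23 rose and none fell in telogen iKO cells (24). The lactate transporter gene Slc16a3 rose 3.03-, 14.2- and 15.9-fold in these comparisons. Both telogen folds rest on the same WT libraries, with 0.482 FPKM in the telogen table and 0.501 in the joint table. They are therefore not independent and start from a low level. Among controls, 11 of the 35 genes were higher and 4 lower in anagen Het than in telogen WT cells. Vegfa rose 2.02-fold in anagen and 3.50-fold in telogen cKO cells, and Pfkfb3 rose 3.47-fold in telogen cKO and 7.38-fold in telogen iKO cells.

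For antigen presentation, more immune cells in the knockout sorts could raise the list, but the larger of both medians of the 18 immune genes was 0.0872, and no immune gene other than Cd74 rose in either 2-group comparison. A rise with Foxc1 loss regardless of stage or driver may also hold in telogen iKO cells. There the median was 0.21, at the 98.4 percentile, but 2 of 15 genes were called, which were H2-T23 and Nlrc5. The WT libraries are also the ones from which the list was in part chosen. In that comparison the immune list had a median of 0.25, at the 99.96 percentile, with 2 of 18 genes called higher (H2-Aa and Ptprc) and none lower. With adjustment over the list alone, 0 were called. By the list median, more immune cells can therefore not be set aside for telogen iKO cells. Whether the rise holds regardless of stage or driver stays open. Whether class I variants of the strains map differently to the reference was not tested.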
